A study of Homo sapiens with 21 samples.

How the data were processed

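Gene expression was measured by RNA-seq in 21 tumour samples from HT1376 cells implanted in the right flank of female CB17 SCID mice aged 6 to 8 weeks. Treatment started 11 to 15 days after implantation, at a mean tumour volume of 139 to 160 mm3, with vehicle or 1 of 6 compounds at 75 mg/kg by mouth daily, and tumours were taken 1 hour after the dose on day 15. Per the labels, tumours were snap-frozen and RNA was extracted with Trizol, and libraries were sequenced on a HiSeq 4000 as paired 150 bp reads, 9 samples per lane. The labels name a TruSeq RNA v2 kit and also call the libraries strand-specific.

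The values are raw counts per Ensembl gene, as deposited by the authors, whose processing notes name STAR 2.7.3a, RSEM 1.3.1 and the hg38 assembly. The counting program, its strand setting, the annotation release and any removal of mouse reads are not given in the sources used here. Each table held 57500 genes, of which 56410 were matched to a symbol through GENCODE 29 and 54784 had the same start and end there. Library totals ran from 9725690 to 25771778 counts, and 31834 to 35733 genes had a count in each library.

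Samples were grouped by the treatment in their labels into 7 groups of 3. Titles of 3 libraries and count column names of 3 libraries carry a resubmission mark (PF-06821497 library 1 against 2, and CPI-1205 libraries 2 and 3 in both), and the 3 PF-06821497 libraries have different numbers in title and column; the group is unaffected.

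Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr by group (21958 genes, holding 99.6% to 99.9% of counts; 9365 genes had 0 counts in every library). TMM factors ran from 0.946 to 1.08. The main test was the edgeR quasi-likelihood test in 1 fit of all libraries with a term per group and robust dispersions (common biological coefficient of variation 0.163, 14 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. Each compound was compared with vehicle, the other 5 with CPI-0209, and valemetostat and MAK683 with tazemetostat, with an overall test among the 6 compounds. Folds against a group with no count use a floor of 3 counts over the group, and with 1 to 3 counts the ratio has a 95% counting interval.

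Gene lists were fixed before the data were examined: PRC2, PRC1 and SWI/SNF subunits, HOX genes, developmental transcription factors, signalling genes of development, genes reported as EZH2-silenced, CDK inhibitors, proliferation, luminal, basal and squamous, EMT, MHC class I, MHC class II, interferon-stimulated, cytokine and chemokine, neuronal, cancer-testis, xenobiotic, cholesterol, hypoxia, stress response, immediate early and heat shock, and p53 genes, and markers of 8 other cell types. They were tested with camera (preset correlation 0.01) on voom values, adjusted over the lists of each comparison. Some genes, such as FLG, stand in several lists, so results of different lists are not independent. Members with a count of calls "adjusted over the list alone" were adjusted within the list. The developmental regulator score is the mean log2 CPM (prior count 2) of 108 tested HOX and developmental transcription factor genes minus the vehicle mean, compared by two-sided exact permutation.

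Genes were named by a rule set before the data were examined: EZH2, EZH1, EED, SUZ12 and ARID1A in the comparisons with vehicle; for each compound against vehicle, among genes with adjusted p under 0.05, a mean of at least 1 CPM in the higher group, a symbol and no overlap between groups, the 10 largest rises and 5 largest falls; for comparisons of compounds, the 5 largest each way; and up to 4 members of each list with the smallest p. MYH4 and the genes named under other observations were named after their values were seen.

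Mouse-tissue reads were followed indirectly, by the median log2 CPM of skeletal muscle markers and by the mean log2 CPM of 50 processed pseudogenes. These 50, of 1330 tested, followed those markers best within groups. This pseudogene measure was made after the data were examined, and the species of the reads was not checked. Alternatives were: no low-count filter; at least 1 CPM in 3 libraries; RLE and upper-quartile scaling; DESeq2; limma-voom; a test against a 1.5-fold change (glmTreat); a fit of only the 2 groups compared; replicate number as a block; a term for, or omission of, the resubmission-marked libraries; each library left out; camera with an estimated correlation and fry; and for the score a prior count of 0.5 and the median over members. The terms from count columns, thinning to the lowest depth, both mouse-read covariates and the omission of libraries for lists were chosen after the data were examined. The pipeline was tested on simulated data with 200 changed genes, all with a mean of at least 1 CPM in vehicle. The simulated comparisons were shaped as tazemetostat and CPI-1205 with vehicle. In them, 2-fold changes were recovered in 80.6% and 70.1% of genes, and 1.5-fold changes in 32.8% and 44.8%. Changes of genes under 1 CPM in vehicle, 28.7% of those tested, were not simulated. The sequence reads were not analysed here.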

Results

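RNA was sequenced from tumours of HT1376, a human bladder carcinoma cell line, grown under the skin of immunodeficient mice, and reads were counted per human gene. The 21 libraries fell into 7 groups of 3: vehicle and 6 inhibitors of PRC2, the polycomb complex that places a repressive methyl mark on histones through its catalytic subunits EZH2 and EZH1. The compounds were CPI-0209, valemetostat, MAK683, tazemetostat, PF-06821497 and CPI-1205. Each was given by mouth at 75 mg/kg daily, and tumours were taken 1 hour after the dose on day 15. The series calls all 6 EZH2 inhibitors, although MAK683 is known to bind EED, another subunit of the complex. Library totals ran from 9725690 counts (CPI-0209 library 3) to 25771778. Between 31834 and 35733 genes had a count in each library. A gene at 0 could stand at up to 0.309 CPM (counts scaled to library size) in the smallest library, from 3 counts, and such floors and all counting intervals cover counting error only. The labels do not state that each library came from a separate animal, so p-values measure the spread between these libraries and nothing wider. Values below are edgeR log2 fold changes ± SE or mean CPM ± SD, with n = 3 per group and 21958 genes tested. Adjusted p-values of single genes are from edgeR and those of gene lists from camera.

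**Figure D1:**
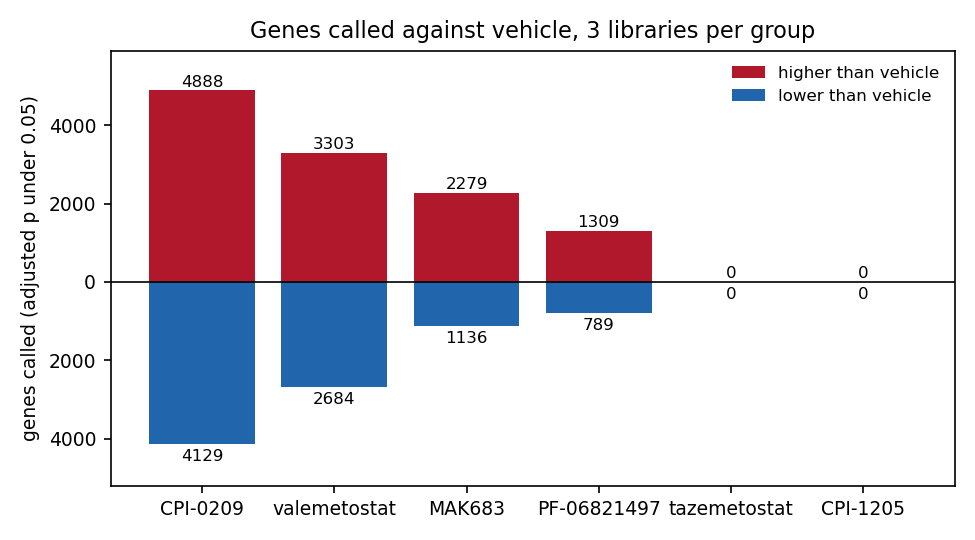
Genes called higher (red, above 0) or lower (blue, below 0) than vehicle at an edgeR adjusted p under 0.05 for each compound, 3 libraries per group. CPI-0209 had 4888 higher and 4129 lower, and tazemetostat and CPI-1205 had 0 in either direction.

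CPI-0209 was compared with vehicle to ask which genes respond to this inhibitor in the tumours. Genes of MHC class II antigen presentation had 14 of 15 tested members higher, 0 lower and a median log2 fold change of 5.37. HLA-DPB1 (ENSG00000223865), a chain of a class II molecule, stood at 38.0 ± 12.5 CPM against 0.832 ± 0.374 in vehicle (5.49 ± 0.39, adjusted p 2.83e-09). HLA-DPA1 rose by 5.36 ± 0.42 and CIITA, the master activator of class II genes, by 3.37 ± 0.30. Cytokine and chemokine genes were higher in 31 of 37 and lower in 2 (median 3.19). Among them CXCL1, a neutrophil attractant, stood at 43.2 ± 7.45 CPM against 0.945 ± 0.325 (5.51 ± 0.35), and LIF (3.98 ± 0.29), CXCL11 (4.40 ± 0.33) and CSF1 (3.18 ± 0.23) were also higher. Adjusted over the list alone, 15 class II genes and 31 cytokine genes were higher and 2 cytokine genes lower. The camera adjusted p was 1.27e-12 for class II and 2.92e-15 for cytokines, and each had adjusted p = 0.101 with an estimated correlation. Markers of macrophages, lymphocytes and endothelium, cells known to express such genes, were higher as well. An indirect measure of mouse-tissue reads, described below with the HOX genes, was also used as a covariate. With it, 14 class II genes (median 4.79) and 27 cytokine genes (median 2.81) were higher and 0 and 2 lower by edgeR. Without CPI-0209 library 3 or vehicle library 3, 1 cytokine gene was lower.

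MHC class I presentation genes were higher in 14 of 22 with CPI-0209 and lower in 1 (median 0.78), with PSMB9, an immunoproteasome subunit, up by 1.77 ± 0.15 and the peptide transporter gene TAP1 by 1.46 ± 0.15. Interferon-stimulated genes were higher in 28 of 49 and lower in 2 (median 0.55), among them IDO1, an enzyme of tryptophan breakdown (6.28 ± 0.48), ZBP1 (4.25 ± 0.36) and the transcription factor IRF1 (1.38 ± 0.13). Adjusted over the list alone, these counts were 15 higher and 1 lower, and 31 higher and 2 lower. The lists had camera adjusted p 6.98e-07 and 8.31e-08, or adjusted p = 0.127 and 0.335 with an estimated correlation. Cancer-testis genes, normally silent outside the germ line, were higher in 19 of 33 and lower in 2, and in 19 and 3 adjusted over the list alone (median 0.89). PAGE1 rose by 3.68 ± 0.21, MAGEA10 by 2.24 ± 0.14 and PRAME by 5.04 ± 0.33, from 0.591 ± 0.112 to 19.6 ± 7.5 CPM. Their camera adjusted p was 4.58e-06, and 0.00471 with an estimated correlation. Neuronal and synaptic genes were higher in 28 of 37 and lower in 2 (29 and 2 adjusted over the list alone; median 1.93), with the ubiquitin hydrolase gene UCHL1 up by 4.64 ± 0.29 and the neurofilament gene NEFM by 4.72 ± 0.41. Camera gave adjusted p 1.85e-07 for this list, and adjusted p = 0.101 with an estimated correlation. By edgeR, 0 neuronal genes and 1 interferon-stimulated gene were lower without CPI-0209 library 3 or vehicle library 2 or 3, and 1 neuronal gene without each of the other libraries compared.

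Developmental regulators that polycomb is known to bind were also higher with CPI-0209. Of 26 tested HOX genes, which pattern the body axis, 25 were higher and 0 lower (25 and 0 adjusted over the list alone; median 3.01). The lists held 39 HOX genes, 152 other transcription factors and 67 signalling genes. Their members near 0 in vehicle were tested only if they had counts in other groups, which favours rises among those tested. HOXB7 rose by 4.70 ± 0.54, from 0.269 ± 0.199 to 7.15 ± 3.12 CPM, HOXA3 by 4.31 ± 0.55, and HOXD11 had a ratio of 168 (counting interval 29.5 to 6680). Other developmental transcription factors were higher in 52 of 82 and lower in 8 (57 and 8 adjusted over the list alone; median 1.85), with TWIST1 at 3.23 ± 0.23, FOXA2 at 2.92 ± 0.24 and WT1 at 5.78 ± 0.58. Signalling genes of development were higher in 29 of 48 and lower in 7 by either adjustment over all genes or adjusted over the list alone (median 1.37), among them the guidance cue gene NTN1 (6.39 ± 0.57) and the Wnt agonist gene RSPO4 (4.79 ± 0.46). The camera adjusted p was 5.29e-08, 2.59e-08 and 0.000225 for the 3 lists, or adjusted p = 0.213, 0.101 and 0.125 with an estimated correlation. A measure made to follow reads from mouse tissue moved with these lists. The species of the reads was not checked, so the measure may also follow a response of the carcinoma cells. It is the mean log2 CPM of 50 processed pseudogenes that follow skeletal muscle genes within groups, and it was 2.29 (SD 1.02) with CPI-0209 and -0.16 (SD 0.45) in vehicle. With this measure as a covariate, 5 HOX genes (median 0.78), 26 transcription factors (0.90) and 12 signalling genes (0.66) were higher. Without CPI-0209 library 3, the numbers were 19, 50 and 27.

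Squamous and metabolic genes were lower with CPI-0209. Basal and squamous genes fell in 31 of 49 and rose in 2 (33 and 2 adjusted over the list alone; median -0.92), with SERPINB13 at -2.10 ± 0.17, the cornified-envelope gene FLG at -3.18 ± 0.28 and the keratin gene KRT4 at -2.60 ± 0.23. Cholesterol synthesis genes, a list that also holds fatty acid genes, fell in 22 of 28 and rose in 0 (median -0.82). Adjusted over the list alone, 24 fell and 0 rose. Among them were SQLE (-1.36 ± 0.16) and the fatty acid desaturase gene SCD (-2.05 ± 0.19). Hypoxia and glycolysis genes fell in 21 of 30 and rose in 2 (22 and 2 adjusted over the list alone; median -0.99), with P4HA1 at -1.62 ± 0.19 and BNIP3L at -1.41 ± 0.17, while the collagen cross-linking gene LOX rose by 2.31 ± 0.34. Proliferation genes fell in 16 of 55 and rose in 1, or 14 and 1 adjusted over the list alone, with a median of -0.17; KIF20A stood at -0.63 ± 0.12 and NUSAP1 at -0.45 ± 0.09. Camera adjusted p was 4.37e-11, 7.31e-12, 3.01e-06 and 0.00526 for the 4 lists in this order, or adjusted p = 0.161, 0.101, 0.335 and 0.368 with an estimated correlation. Without any vehicle library or CPI-0209 library 2, 1 basal and squamous gene was higher.

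**Figure D2:**
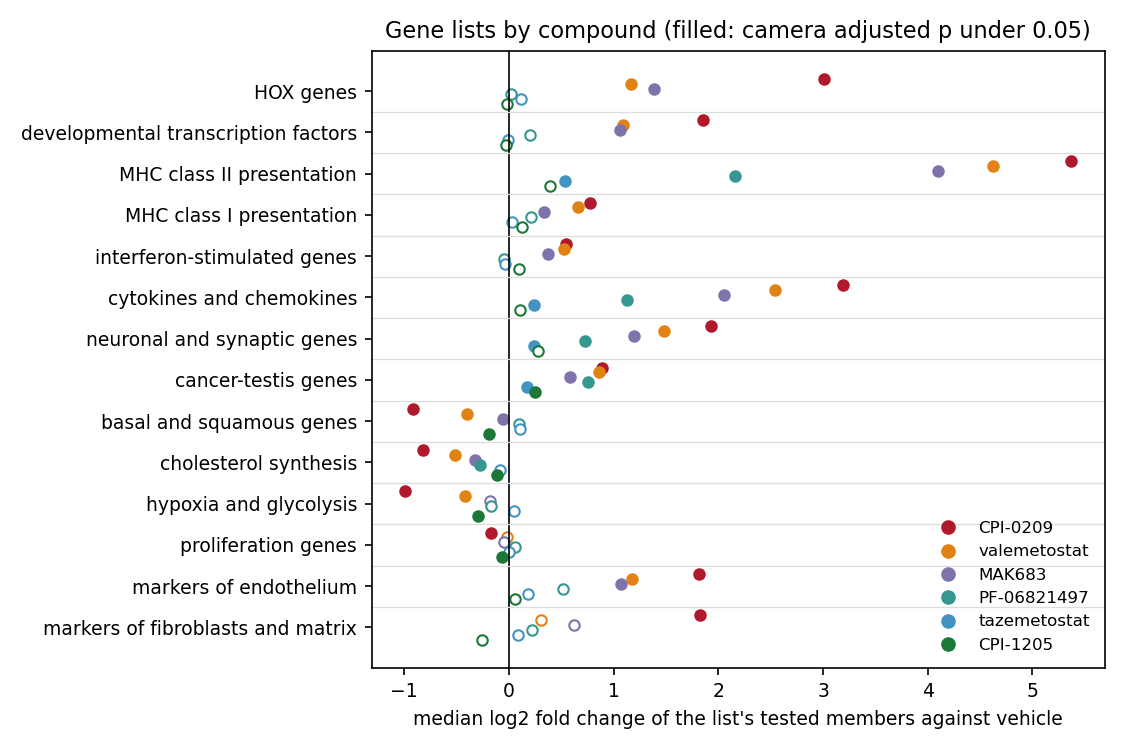
Median log2 fold change against vehicle (horizontal axis) of the tested members of 14 gene lists, by compound, with filled points for a camera adjusted p under 0.05. MHC class II presentation ran from 0.39 with CPI-1205 to 5.37 with CPI-0209, and no filled point changed sign under upper-quartile or RLE scaling.

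Other lists did not pass camera with CPI-0209, although single members did. Luminal urothelial genes split into 11 higher and 12 lower of 35 (11 and 15 adjusted over the list alone; median -0.21), with the fatty acid carrier gene FABP4 at 3.37 ± 0.33, the receptor gene FGFR3 at -1.62 ± 0.17 and the claudin gene CLDN7 at 0.97 ± 0.13. PRC2 subunits were higher in 5 and lower in 3 of 15 (5 and 4 adjusted over the list alone), with EZHIP, a known inhibitor of PRC2, up by 2.98 ± 0.29 and AEBP2 down (-0.91 ± 0.15). PRC1 subunits were higher in 9 and lower in 6 of 25 by both adjustments, the latter adjusted over the list alone, with CBX2 at 1.97 ± 0.21. SWI/SNF subunits were higher in 2 and lower in 9 of 25 by both adjustments, with SMARCD3 at 2.24 ± 0.34. Genes reported as EZH2-silenced in tumours were higher in 11 and lower in 8 of 31 by both adjustments, with IL24 at 4.59 ± 0.35 and TIMP3 at -1.36 ± 0.14. EMT genes were higher in 13 and lower in 7 of 25 by both adjustments (median 0.74, camera adjusted p 0.0619), and the median was -0.21 with the processed pseudogene covariate. Of 8 CDK inhibitor genes, 2 were higher and 3 lower by both adjustments, with CDKN1C at 1.67 ± 0.19 and CDKN2B at -0.83 ± 0.11. Xenobiotic response genes were higher in 6 and lower in 8 of 27 (6 and 9 adjusted over the list alone), with the cystine transporter gene SLC7A11 at -2.37 ± 0.23 and the efflux pump gene ABCG2 at -1.32 ± 0.13. Stress and unfolded protein response genes were higher in 5 and lower in 2 of 24 by both adjustments, with CEBPB at 0.74 ± 0.11. Immediate early and heat shock genes were higher in 6 and lower in 8 of 28 by both adjustments, with EGR1 at -1.66 ± 0.20, and p53 target genes were higher in 6 and lower in 5 of 22 (7 and 5 adjusted over the list alone), with GDF15 at 1.44 ± 0.24 and XPC at -0.87 ± 0.13. Without CPI-0209 library 2, 2 stress genes and 3 p53 target genes were higher, and 3 PRC2 subunits were higher without CPI-0209 library 3 or vehicle library 1 or 2. Without CPI-0209 library 1 or 3 or vehicle library 1 or 2, 1 stress gene was lower.

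Markers of cell types that a tumour can hold besides the carcinoma cells also differed between CPI-0209 and vehicle. Endothelial markers were higher in 8 of 11 and lower in 2 (9 and 2 adjusted over the list alone; median 1.82), with PECAM1, an adhesion molecule, at 27.4 ± 4.41 against 2.00 ± 0.434 CPM (3.78 ± 0.25) and the junction gene CLDN5 at 4.28 ± 0.48. Macrophage and granulocyte markers were higher in 8 of 14 and lower in 1 by both adjustments (median 1.38), with ADGRE1 at 3.16 ± 0.29 and LAPTM5 at 1.77 ± 0.18, and lymphocyte markers were higher in 5 of 5 by both adjustments (median 2.25), with CD3E at 2.23 ± 0.29. Fibroblast and matrix markers were higher in 11 of 20 and lower in 3 (13 and 3 adjusted over the list alone; median 1.82), with THY1 at 6.17 ± 0.47, COL6A1 at 5.83 ± 0.52 and the microfibril gene FBN1 at -2.07 ± 0.20. Skin keratinocyte and hair markers fell in 5 of 8 and rose in 0 (6 and 0 adjusted over the list alone; median -1.60), with KRT10 at -2.63 ± 0.24 and KRT1 at -3.74 ± 0.36. By camera these had adjusted p 0.00295, 0.00295, 0.00213, 0.00892 and 0.00114 in order of mention, or adjusted p = 0.127, 0.125, 0.101, 0.368 and 0.125 with an estimated correlation. The keratinocyte list shares members, such as FLG, with the basal and squamous list. Its fall is therefore not independent of the fall of that list, and need not come from cells other than the carcinoma cells. Skeletal muscle markers were higher in 4 and lower in 1 of 11 (8 and 1 adjusted over the list alone; median 3.55, camera adjusted p 0.15), with TTN at 3.43 ± 0.91 and TNNT3 at -1.01 ± 0.15. Without CPI-0209 library 3, 0 muscle markers (median 1.55) and 8 fibroblast markers were higher by edgeR, TTN then standing at 2.21, and with the pseudogene covariate 0 (median -1.67) and 7. Without vehicle library 1 or 2, 1 muscle marker was higher, and without vehicle library 2, 1 endothelial marker was lower. In CPI-0209 library 3 the muscle myosin gene MYH4, named after its values were seen, stood at 243.5 CPM, against 36.8 and 8.4 in the other libraries of its group. Of adipocyte markers, 4 were tested, too few for camera, with FABP4 as above and LPL at 2.62 ± 0.35; of red blood cell markers 2 were tested, with HBA2 at 1.62 ± 0.68 and HBB at 1.19 ± 0.75, not past the threshold (HBA2 passed at 2.02 without CPI-0209 library 2 and at 2.21 without vehicle library 2).

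The largest single changes with CPI-0209 by fitted log2 fold change, chosen by a rule fixed before the data were examined, included genes with no count in vehicle. Lower bounds are given for these, so their rank against other genes is uncertain. TFF1 (ENSG00000160182, GRCh38 chromosome 21, 42362282 to 42366594, minus strand), a secreted mucosal peptide gene, was at least 392-fold higher, at 17.97 ± 6.72 CPM. The chemokine genes CXCL9 and PPBP were at least 63.3-fold and 46.1-fold higher, taking 3 counts over the vehicle group as the floor. KCNK15 was at least 38.3-fold, FOXN4 at least 34.3-fold, GNGT2 at least 31.9-fold, the pseudogene CYP4F59P at least 30.9-fold and the antisense gene TBX5-AS1 at least 40.7-fold higher. Antisense genes and paralogs are uncertain, since the strand used in counting is not given. GGT5 rose by 8.29 ± 0.70 and ELFN2 by 7.96 ± 0.76. Among the falls, the laminin gene LAMB4 went from 55.1 ± 7.10 to 2.40 ± 1.53 CPM (-4.56 ± 0.43), and VIT (-4.50 ± 0.41), the desmosomal gene DSC1 (-4.43 ± 0.47) and LINC03013 (-4.75 ± 0.74) fell as far. The arginase gene ARG1 had a ratio of 0.0307 (counting interval 0.00366 to 0.114).

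In all, 4888 genes were higher and 4129 lower with CPI-0209, 41.1% of those tested, and the medians of the called genes were 1.93 and -0.67. Of the called genes, 3761 higher and 1046 lower changed at least 2-fold. Groups did not overlap in 55.0% of genes, where chance gives 10%. The share of calls that were higher was 54.2%, against 67.5% with upper-quartile scaling, which moved the median of all genes from -0.02 to 0.12. With the pseudogene covariate, 5505 of the 9017 called genes were called in the same direction. Taking genes with no vehicle count at their bound moved 7 of the 180 list medians against vehicle, by at most 0.02.

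Valemetostat, known to inhibit both EZH2 and EZH1, was set against vehicle with the same question. MHC class II genes were higher in 13 of 15 and lower in 0 (13 adjusted over the list alone; median 4.62), with HLA-DPB1 at 22.1 ± 10.8 CPM (4.71 ± 0.39, adjusted p 3.77e-08) and HLA-DQB1 at 4.62 ± 0.43. Cytokine genes were higher in 30 of 37 and lower in 0 by both adjustments, the latter adjusted over the list alone (median 2.54), with the interferon-induced chemokine gene CXCL10 at 6.33 ± 0.48 and CXCL1 at 4.43 ± 0.35. Neuronal genes were higher in 20 of 37 (UCHL1 3.79 ± 0.29), MHC class I genes in 14 of 22 (TAP1 1.18 ± 0.15) and interferon-stimulated genes in 25 of 49 (IDO1 5.42 ± 0.48), with 0, 1 and 1 lower; adjusted over the list alone, 20, 15 and 26 were higher. Camera adjusted p for these 5 lists was 6.62e-14, 7.8e-15, 6.02e-08, 1.98e-07 and 1.11e-08, or adjusted p = 0.113, 0.107, 0.107, 0.168 and 0.328 with an estimated correlation. Cancer-testis genes were higher in 19 of 33 and lower in 2, or 19 and 3 adjusted over the list alone (PRAME 4.71 ± 0.33; camera adjusted p 1.32e-07, and 0.00102 with an estimated correlation). Without valemetostat library 1, 1 of them was lower.

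Developmental transcription factors were higher in 36 of 82 and lower in 7 with valemetostat (41 and 8 adjusted over the list alone; median 1.09), with TWIST1 at 2.30 ± 0.22 and SP8 at a ratio of 127 (counting interval 22.4 to 5070). HOX genes were higher in 5 of 26 (5 adjusted over the list alone; median 1.16), with HOXA3 at 2.68 ± 0.60, and signalling genes of development in 19 of 48, with 5 lower (21 and 6 adjusted over the list alone; NTN1 5.20 ± 0.57). These lists had camera adjusted p 9.39e-06, 0.00201 and 0.00725, or adjusted p = 0.179, 0.526 and 0.243 with an estimated correlation. The mouse-tissue measure was 0.65 in this group, and with it as a covariate 32 transcription factors (median 0.74) and 4 HOX genes (median 0.55) were higher. Without vehicle library 3, 4 transcription factors were lower, and signalling genes numbered 2 lower without valemetostat library 1 and 3 without valemetostat library 3 or vehicle library 2 or 3. Cholesterol synthesis genes fell in 18 of 28 (SCD -1.46 ± 0.18), basal and squamous genes in 18 of 49 with 1 higher (FLG -2.58 ± 0.26) and hypoxia genes in 12 of 30 with 2 higher (BNIP3L -1.04 ± 0.17), or 20, 19 and 14 lower adjusted over the list alone. Without valemetostat library 3, 9 cholesterol genes and 4 hypoxia genes were lower, and hypoxia genes numbered 6 without valemetostat library 1 and 7 without vehicle library 2. By camera, adjusted p was 2.2e-08, 9.9e-07 and 0.00201, or adjusted p = 0.168, 0.328 and 0.57 with an estimated correlation. Xenobiotic response genes passed in the downward direction, with 3 higher and 8 lower of 27 (4 and 9 adjusted over the list alone; SLC7A11 -1.97 ± 0.22; camera adjusted p 0.0473, adjusted p = 0.191 with an estimated correlation). Of these, 4 were lower without valemetostat library 1 or vehicle library 3, and 5 lower and 1 higher without valemetostat library 3. Endothelial markers were higher in 7 and lower in 2 of 11 (PECAM1 3.26 ± 0.25), macrophage markers in 5 and 1 of 14 (ADGRE1 2.76 ± 0.29) and lymphocyte markers in 5 and 0 of 5 (CD3D 2.30 ± 0.43), and keratinocyte markers fell in 5 of 8 (KRT10 -2.25 ± 0.24). Adjusted over the list alone, 7, 8 and 5 were higher and 6 keratinocyte markers lower. Over all genes, 4 endothelial markers were higher without valemetostat library 1, and 3 macrophage and 3 lymphocyte markers without vehicle library 2. By edgeR, 1 endothelial marker was lower without valemetostat library 1 or 3 or vehicle library 3, and 0 macrophage markers without valemetostat library 1 or vehicle library 2. Their camera adjusted p was 0.005, 0.0108, 0.00273 and 0.000427, or adjusted p = 0.179, 0.191, 0.107 and 0.129 with an estimated correlation.

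By the same rule, the rises named with valemetostat include TFF1 (at least 93.5-fold) and CXCL9 (at least 54.8-fold). They also include TRIM60 (ratio 161, counting interval 28.5 to 6410), the growth factor gene BMP5 (123, 33.7 to 1030) and the kinesin gene KIF19 (130, 22.8 to 5160). GGT5 (6.55 ± 0.72), UBD (6.54 ± 0.52), the sialyltransferase gene ST6GAL1 (6.53 ± 0.53) and ELFN2 (6.34 ± 0.78) rose as well. LINC03013 (-4.38 ± 0.67), LINC01181 (-4.12 ± 0.48), DSC1 (-3.90 ± 0.44), LAMB4 (-3.85 ± 0.40) and LINC02518 (-3.75 ± 0.30) fell furthest. In total 3303 genes were higher and 2684 lower (median 1.67 and -0.64), 2401 and 625 of them by at least 2-fold, and groups did not overlap in 47.0% of genes against 10% by chance. Without vehicle library 3, 1608 were lower. The higher share was 55.2% of calls, and 67.2% with upper-quartile scaling.

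MAK683, which binds EED, was compared with vehicle in the same way. MHC class II genes were higher in 12 of 15 (13 adjusted over the list alone; median 4.10), with HLA-DPB1 at 16.1 ± 3.15 CPM (4.25 ± 0.39, adjusted p 2.78e-07) and HLA-DRB1 at 4.10 ± 0.43. Cytokine genes were higher in 25 of 37 (30 adjusted over the list alone; median 2.06), with CXCL1 at 3.65 ± 0.35 and LIF at 2.56 ± 0.28, and neuronal genes in 15 of 37 (17 adjusted over the list alone; UCHL1 3.32 ± 0.29). None of these 3 lists had a member called lower by edgeR, and their camera adjusted p was 7.47e-16, 1.47e-16 and 5.19e-08, or adjusted p = 0.096 for each with an estimated correlation. Cancer-testis genes were higher in 14 of 33 (17, and 1 lower, adjusted over the list alone; PRAME 3.88 ± 0.33; camera adjusted p 4.55e-06, and 0.00314 with an estimated correlation). MHC class I genes were higher in 10 of 22 and lower in 1 (HLA-B 1.03 ± 0.20), and interferon-stimulated genes in 11 of 49 and lower in 1 (IDO1 2.90 ± 0.50), or 12 and 15 higher adjusted over the list alone, at camera adjusted p 0.000531 and 6.35e-06, or adjusted p = 0.285 and 0.447 with an estimated correlation. Interferon-stimulated genes numbered 6 higher without MAK683 library 1 or vehicle library 3, and 7 without MAK683 library 2 or vehicle library 1 or 2. By edgeR, 0 of them were lower without MAK683 library 1 or 3 or vehicle library 2 or 3, and 0 MHC class I genes without MAK683 library 2 or vehicle library 3.

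Developmental transcription factors were higher in 30 of 82 and lower in 5 with MAK683 (39 and 6 adjusted over the list alone; median 1.06), with TWIST1 at 1.99 ± 0.22, TBX1 at 2.15 ± 0.26 and EOMES at a ratio of 33.7 (counting interval 11.1 to 167). HOX genes were higher in 7 of 26 (8 adjusted over the list alone; median 1.38), with HOXB7 at 3.38 ± 0.55, signalling genes of development in 16 of 48 with 2 lower (RSPO4 3.59 ± 0.48), and genes reported as EZH2-silenced in 10 of 31 with 4 lower (CCND2 2.43 ± 0.30), or 19 and 11 adjusted over the list alone for the last pair. These had camera adjusted p 6.06e-08, 3.23e-05, 0.00015 and 0.00687, or adjusted p = 0.125, 0.36, 0.127 and 0.19 with an estimated correlation. The mouse-tissue measure was 0.96 in this group, and with it as a covariate 22 transcription factors (median 0.60) and 3 HOX genes (median 0.61) were higher. Without MAK683 library 1, 3 HOX genes were higher (median 0.76), as were 3 without vehicle library 2 and 4 without MAK683 library 3 or vehicle library 1. Without vehicle library 1, 6 of the genes reported as EZH2-silenced were higher. Transcription factors numbered 3 lower without MAK683 library 1 or vehicle library 2 or 3, and signalling genes 1 lower without MAK683 library 1 or vehicle library 1 or 3. PRC1 subunits (8 higher and 1 lower of 25, 8 and 2 adjusted over the list alone, CBX2 1.81 ± 0.21) and EMT genes (7 higher and 2 lower of 25, 8 and 2 adjusted over the list alone, the matrix gene TNC 1.70 ± 0.17) also passed, at camera adjusted p 0.0159 and 0.0166, or adjusted p = 0.22 and 0.476 with an estimated correlation. The EMT median was 0.56, and with the covariate 0.09, with 6 higher and 3 lower. Of PRC1 subunits, 5 were higher without vehicle library 1 and 0 lower by edgeR without MAK683 library 3. Of EMT genes, 1 was lower without MAK683 library 3 or vehicle library 3. Cholesterol synthesis genes fell in 4 of 28 (SCD -1.14 ± 0.18) and basal and squamous genes in 11 of 49 with 1 higher (FLG -1.49 ± 0.25), or 6 and 11 adjusted over the list alone, at camera adjusted p 1.67e-05 and 0.0309, or adjusted p = 0.271 and 0.694 with an estimated correlation. These falls changed with single libraries. Cholesterol genes numbered 1 lower without MAK683 library 1 or vehicle library 3, and 2 without MAK683 library 2 or vehicle library 1 or 2. Basal and squamous genes, with a median of -0.06, numbered 5 lower without MAK683 library 1 (median 0.10) or vehicle library 3, 6 without MAK683 library 2, and 7 without MAK683 library 3 or vehicle library 2. Markers of endothelium were higher in 5 and lower in 1 of 11 (PECAM1 3.48 ± 0.25), of macrophages in 3 of 14 (ADGRE1 1.61 ± 0.30) and of lymphocytes in 3 of 5 (NCR1 2.61 ± 0.64, and 2.15, not past the threshold, without MAK683 library 1), and of keratinocytes lower in 4 of 8 (KRT10 -1.33 ± 0.23); adjusted over the list alone, these counts were 7, 3, 4 and 4. Over all genes, 1 lymphocyte marker was higher without MAK683 library 1 or 3 or vehicle library 1 or 2, and 3 endothelial markers without MAK683 library 2, while 0 endothelial markers were lower by edgeR without MAK683 library 1 or vehicle library 2. Tested by camera, adjusted p was 0.00605, 0.0398, 0.0148 and 0.0148, or adjusted p = 0.19, 0.285, 0.125 and 0.266 with an estimated correlation.

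With MAK683, TFF1 was at least 71.5-fold higher. HOXD11 (ratio 95, counting interval 16.5 to 3800), TRIM60 (85.1, 14.8 to 3410), the orphan receptor gene GPR50 (71.5, 19.4 to 598) and BMP5 (47.5, 12.7 to 399) were higher too. ST6GAL1 (6.29 ± 0.53), GGT5 (5.84 ± 0.74), ELFN2 (5.78 ± 0.80), the imprinted noncoding gene MEG3 (5.69 ± 0.50) and HLA-DQA1 (5.24 ± 0.57) completed the rises named by rule. LINC03013 (-3.14 ± 0.59), DSC1 (-2.86 ± 0.41), LAMB4 (-2.78 ± 0.38), LINC02518 (-2.52 ± 0.27) and the protease gene ADAMTS5 (-2.5 ± 0.38) fell furthest. Calls came to 2279 higher and 1136 lower (median 1.70 and -0.61), 1778 and 215 by at least 2-fold, and groups did not overlap in 36.0% of genes against 10% by chance. The lower count was 696 and 639 without vehicle libraries 2 and 3, and 679 and 655 without MAK683 libraries 1 and 3.

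**Figure D3:**
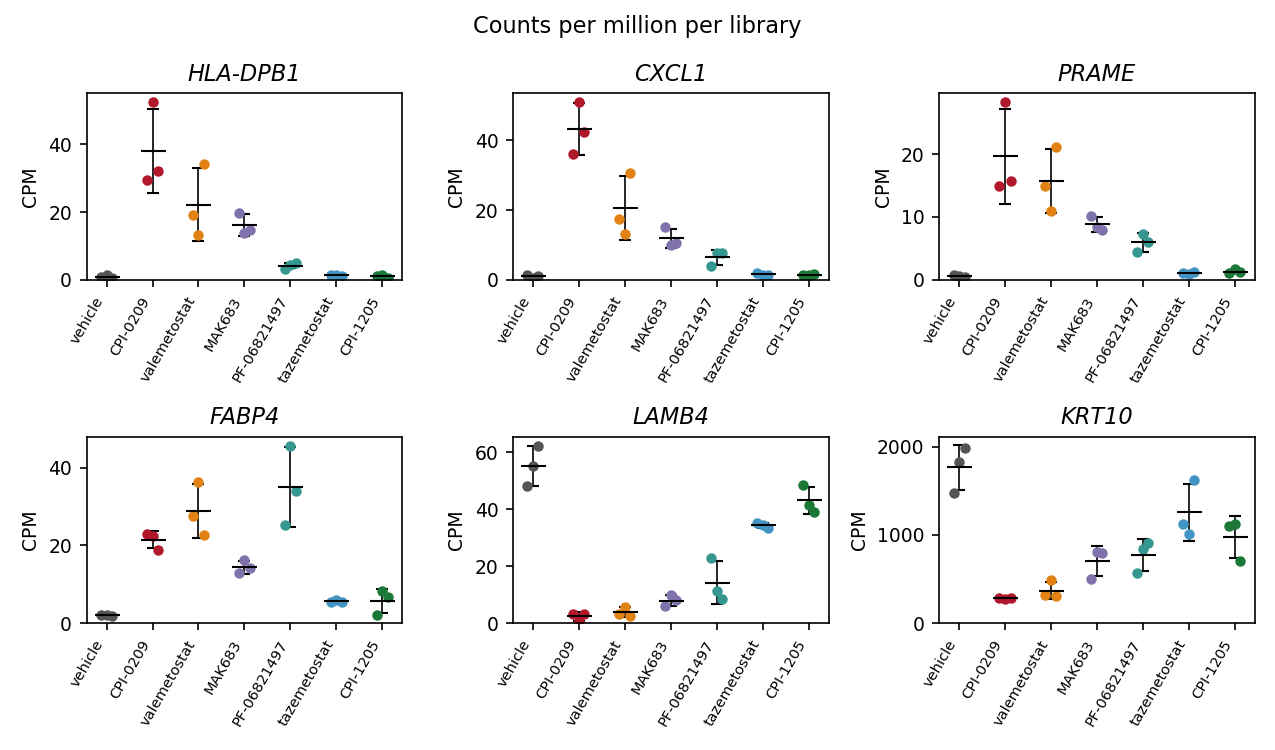
CPM per library (points) with the group mean and SD (black, n = 3) for 6 genes in the 7 groups. HLA-DPB1 stood at 0.832 in vehicle and 38.0 with CPI-0209, and LAMB4 at 55.1 and 2.40.

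PF-06821497 against vehicle gave a smaller set of calls. MHC class II genes were higher in 12 of 15 (12 adjusted over the list alone; median 2.16), with HLA-DPB1 at 4.16 ± 0.795 CPM (2.29 ± 0.40, adjusted p 0.000799) and HLA-DRA at 2.61 ± 0.48. Cytokine genes were higher in 23 of 37 (25 adjusted over the list alone; median 1.13), with CXCL1 at 2.76 ± 0.35 and CXCL10 at 3.81 ± 0.48, and neuronal genes in 11 of 37 (14 adjusted over the list alone), with UCHL1 at 2.67 ± 0.29. Camera adjusted p for the 3 lists was 1.19e-08, 8.86e-13 and 1.37e-05, or adjusted p = 0.345, 0.296 and 0.296 with an estimated correlation. Cancer-testis genes were higher in 15 of 33 (18 adjusted over the list alone; median 0.76), with PAGE1 at 2.35 ± 0.21 and PRAME at 3.31 ± 0.33 (camera adjusted p 4.08e-10, and 0.000153 with an estimated correlation). Cholesterol synthesis genes, with the fatty acid synthase gene FASN at -0.67 ± 0.15, fell in 4 of 28. Macrophage markers were higher in 4 of 14 (ADGRE1 1.64 ± 0.30) and keratinocyte markers lower in 2 of 8 (FLG -1.40 ± 0.25). Adjusted over the list alone, these 3 lists had 6, 5 and 3. Their camera adjusted p was 4.75e-05, 0.0456 and 0.0456, or adjusted p = 0.448 for each with an estimated correlation. Neuronal genes numbered 6 and 7 without vehicle library 2 and PF-06821497 library 1. Cholesterol genes numbered 2 lower without vehicle library 1 or PF-06821497 library 2 or 3 and 1 without vehicle library 3, and macrophage markers 1 higher without vehicle library 3 and 2 without PF-06821497 library 3.

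HOX genes did not pass with PF-06821497: edgeR called 0 of 26, over all genes and adjusted over the list alone, with a median of 0.02 (camera adjusted p 0.86). The median was -0.17 with the processed pseudogene covariate and 0.45, over 32 tested genes, without the 3 libraries that carry a resubmission mark in their count column. Developmental transcription factors were higher in 5 and lower in 2 of 82 (TWIST1 1.27 ± 0.22, GATA2 -0.52 ± 0.10; 5 and 2 also adjusted over the list alone; camera adjusted p 0.313). Transcription factors numbered 2 higher without vehicle library 2 and 3 without vehicle library 3 or PF-06821497 library 2, and 4 lower without PF-06821497 library 2 and 1 without vehicle library 3 or PF-06821497 library 3. BMP5 rose (ratio 81.5, counting interval 22.2 to 679), as did ANKRD30A (4.72 ± 0.58), FDCSP (4.64 ± 0.52), EFHC2 (4.48 ± 0.56), the Wnt-pathway ligand gene NDP (4.29 ± 0.51), ST6GAL1 (4.27 ± 0.60) and the monoamine oxidase gene MAOB (4.25 ± 0.44). GNG11 (4.24 ± 0.69), FABP4 (4.07 ± 0.33, to 34.9 ± 10.3 from 2.08 ± 0.156 CPM) and the chloride channel gene CFTR (4.0 ± 0.77) completed the rises named by rule. LINC03013 (-2.99 ± 0.57), LINC02518 (-2.39 ± 0.26), ADAMTS5 (-2.38 ± 0.37), DSC1 (-2.18 ± 0.39) and the antisense gene BAALC-AS2 (-2.17 ± 0.36) fell furthest. There were 1309 higher and 789 lower calls (median 1.31 and -0.61), 840 and 121 by at least 2-fold, and groups did not overlap in 27.2% of genes against 10% by chance. Without vehicle libraries 2 and 3, 853 and 750 were higher and 469 and 291 lower, and without PF-06821497 library 3, 423 were lower. With the muscle marker covariate 1215 were lower.

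Tazemetostat, which binds EZH2, gave no gene an edgeR adjusted p under 0.05 against vehicle, the smallest being 0.0815. At an unadjusted edgeR p under 0.05, 491 genes were higher and 156 lower. These 647 of 21958 tested genes are below the share of 0.05 that chance alone would give on average. DESeq2 called 1 higher and limma-voom 0. A term for the resubmission mark in the titles gave 1 higher, and omission of the libraries marked by title or by count column 3. HLA-DPB1 stood at 0.70 ± 0.44, CXCL10 at 1.66 ± 0.52, UCHL1 at 0.88 ± 0.32 and PAGE1 at 0.71 ± 0.21, each with an edgeR adjusted p of 1. As lists, cytokine genes (median 0.24, camera adjusted p 0.000204), neuronal genes (0.24, 0.00282), cancer-testis genes (0.17, 0.00833) and MHC class II genes (0.53, 0.0137) passed camera upward. Adjusted p = 0.89, 0.799, 0.0887 and 0.942 with an estimated correlation. No list had a member called over all genes; adjusted over the list alone, 1 luminal gene and 1 lymphocyte marker were higher and 0 members of the other lists by edgeR. HOX genes had a median of 0.11 and developmental transcription factors of -0.01. Groups did not overlap in 10.9% of genes, where chance gives 10%. The number of lists was 2 without vehicle library 3, 7 without tazemetostat library 1 and 2 without tazemetostat library 2, and 1 gene was called higher without vehicle library 2 or without tazemetostat library 2.

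CPI-1205 likewise gave 0 edgeR calls against vehicle, with a smallest adjusted p of 0.279. At an unadjusted p under 0.05, 1326 genes were higher and 1387 lower; DESeq2 called 6 higher and 37 lower, and limma-voom 0. Of the 3 CPI-1205 libraries, 2 carry a resubmission mark. With a term for the mark in the titles, 13 genes were higher and 17 lower, and with a term for the mark in the count columns 0 and 0 by edgeR. Without the marked libraries, 57 were higher and 169 lower by title and 74 and 185 by count column, which leaves 1 library of CPI-1205, assumed to vary like the other groups. PAGE1 stood at 0.90 ± 0.21, CCL5, a lymphocyte attractant, at 1.00 ± 0.28, EGR1 at -0.91 ± 0.19 and KRT10 at -0.85 ± 0.23, each with adjusted p 0.279. Cancer-testis genes passed camera upward (median 0.25, adjusted p 4.47e-05, and 0.00671 with an estimated correlation). Basal and squamous genes (median -0.19, 7.94e-06), hypoxia genes (-0.29, 7.94e-06), immediate early and heat shock genes (-0.22, 0.000266), cholesterol synthesis genes (-0.11, 0.00367) and stress response genes (-0.12, 0.00367) passed camera downward, as did keratinocyte markers (0.0127), proliferation genes (0.0278) and EMT genes (0.0278). Adjusted p = 0.574 for cholesterol synthesis, 0.637 for proliferation and EMT and 0.49 for the other 5 lists with an estimated correlation. Most of these falls shrank without the libraries marked in their count column, and hypoxia (0.05) and stress response genes (0.07) turned. The medians were then 0 for basal and squamous genes, -0.07 for immediate early, -0.24 for cholesterol synthesis, -0.20 for keratinocyte, -0.03 for proliferation and -0.01 for EMT genes, and 0.44 for cancer-testis genes. Adjusted over the list alone, edgeR called 6 cancer-testis genes higher, and 2 members each of the basal and squamous, immediate early, keratinocyte and CDK inhibitor lists lower, and single members of 5 other lists. Groups did not overlap in 20% of genes, where chance gives 10%. The number of lists was 15 without vehicle library 2 and 14 without CPI-1205 library 2, 1 gene was higher without CPI-1205 library 1, and 3 and 1 genes were lower without CPI-1205 libraries 1 and 2.

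Single genes of the targeted complex, and ARID1A for context, were also compared. EZH2 was higher with CPI-0209 (0.27 ± 0.10, adjusted p 0.0362), valemetostat (0.31 ± 0.10) and MAK683 (0.31 ± 0.10), and stood at 0.13 ± 0.10 with tazemetostat, 0.25 ± 0.10 with PF-06821497 and 0.00 ± 0.10 with CPI-1205, not past the threshold. EED was higher with CPI-0209 (0.56 ± 0.13) and valemetostat (0.38 ± 0.13), and EZH1 was lower with CPI-0209 (-0.38 ± 0.11). The EZH2 calls and the EED call with valemetostat were lost without single libraries. EZH2 stood at 0.24 to 0.26 with CPI-0209 without vehicle library 2 or 1, at 0.18 without CPI-0209 library 3, at 0.27 to 0.30 with valemetostat without vehicle library 1 or 2 or valemetostat library 3, and at 0.29 to 0.33 with MAK683 without any vehicle library or MAK683 library 1 or 3, each no longer past the threshold. EED with valemetostat (0.32 to 0.39) was not past it without any vehicle library or valemetostat library 3. SUZ12 and ARID1A, a SWI/SNF gene, passed with none of the 6 compounds by edgeR.

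All compounds were given at the same dose and schedule, so they were also compared with each other. CPI-0209, the compound that the series lists ahead of the others, was the reference. No drug level or histone methylation value was available here, so an equal dose need not mean equal inhibition of PRC2. Valemetostat and CPI-0209 gave 0 edgeR calls, with a smallest adjusted p of 0.0833; 753 genes were higher and 1955 lower at an unadjusted p under 0.05, DESeq2 called 325 genes and limma-voom 50. Lists still moved apart: HOX genes had a median of -1.88 and 20 of 26 lower adjusted over the list alone, cytokine genes -0.65 and 18 of 37, and basal and squamous genes 0.43 and 22 of 49 higher. Camera adjusted p was 7.72e-16, 3.4e-16 and 7.72e-16, or adjusted p = 0.108 for each with an estimated correlation. Without CPI-0209 library 1, 531 genes were called, and without valemetostat library 3, 319. The HOX difference goes with the mouse-tissue measure, 0.65 with valemetostat against 2.29 with CPI-0209, and with this measure as a covariate the HOX median was -0.30.

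MAK683 differed from CPI-0209 in 1993 genes, 885 higher and 1108 lower. Basal and squamous genes were higher in 30 of 49 (KRT4 2.24 ± 0.23) and cholesterol synthesis genes in 17 of 28. Cytokine genes were lower in 23 of 37 (IL6 -3.08 ± 0.39), MHC class II genes in 11 of 15 (HLA-DPB1 -1.24 ± 0.30) and interferon-stimulated genes in 9 of 49 (IDO1 -3.38 ± 0.39). Adjusted over the list alone, these counts were 34, 20, 26, 13 and 9. In this order camera gave adjusted p 1.1e-23, 1.66e-15, 1.31e-17, 5.02e-12 and 9.89e-06, or adjusted p = 0.0624, 0.0624, 0.0624, 0.0957 and 0.404 with an estimated correlation. The class II genes, with a median of -1.21, numbered 1 lower without MAK683 library 2 or 3 or CPI-0209 library 2 and 5 without CPI-0209 library 3, and 2 with the processed pseudogene covariate (median -0.84). Without MAK683 library 3, 19 basal and squamous and 7 cholesterol genes were higher, and cholesterol genes numbered 8 and 9 without CPI-0209 libraries 2 and 3. The genes furthest higher were PLA2G3 (2.75 ± 0.59), CDHR1 (2.5 ± 0.47), GPR15LG (2.44 ± 0.55) and the antisense genes HIF1A-AS3 (ratio 18.2, counting interval 5.95 to 90.4) and FAM181A-AS1 (2.48 ± 0.45). Furthest lower were CLEC4E (ratio 0.0155, 0.000386 to 0.0902), OR2I1P (-5.12 ± 0.61), the interleukin receptor gene IL2RA (-4.22 ± 0.68), MUC13 (-4.14 ± 0.61) and MYH6 (-4.02 ± 1.05). Without CPI-0209 library 2, PLA2G3 (2.53), GPR15LG (2.26), MYH6 (-2.73) and HLA-DPB1 (-0.93) were not past the threshold; nor were GPR15LG (2.11), HLA-DPB1 (-1.13) and MYH6 (-3.37) without MAK683 library 2, or HLA-DPB1 (-1.20) and MYH6 (-4.63) without MAK683 library 3. The total was 941 and 933 without CPI-0209 libraries 2 and 3, and 685 without MAK683 library 3.

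Tazemetostat, PF-06821497 and CPI-1205 differed from CPI-0209 in 8130, 4955 and 7736 genes, with 3667, 1901 and 3359 of them higher. With the processed pseudogene covariate the totals were 6019, 2292 and 3595. MHC class II genes were lower in 14, 13 and 14 of 15 (HLA-DPB1 -4.79 ± 0.37, -3.19 ± 0.33 and -5.24 ± 0.38; 14, 13 and 14 adjusted over the list alone), with adjusted p = 0.0784, 0.0725 and 0.083 with an estimated correlation after camera adjusted p 2.63e-14, 4.02e-17 and 8.43e-14. HOX genes were lower in 25, 25 and 24 of 26 (26, 25 and 25 adjusted over the list alone; camera adjusted p 3.58e-09, 4.01e-12 and 2.25e-09; adjusted p = 0.17, 0.0954 and 0.173 with an estimated correlation). The mouse-tissue measure was -0.07, -0.07 and -0.41 in these groups against 2.29 with CPI-0209, and with it as a covariate 5, 3 and 2 HOX genes were lower, the medians going from -2.99, -2.97 and -3.33 to -0.92, -0.93 and -0.91. Without CPI-0209 library 3, 16 HOX genes were lower with PF-06821497, and without the libraries marked in their count column 12 of 32 with CPI-1205. Basal and squamous genes were higher in 34, 35 and 27 of 49 (38, 37 and 29 adjusted over the list alone; camera adjusted p 2.63e-14, 2.68e-19 and 2.66e-08; adjusted p = 0.106, 0.0725 and 0.252 with an estimated correlation). With the covariate, 14, 13 and 13 class II genes were lower and 26, 23 and 16 basal and squamous genes higher. With tazemetostat, HIF1A-AS3 (ratio 28.4, counting interval 9.52 to 140), ARG1 (28.8, 7.76 to 242), VIT (3.95 ± 0.41), PLA2G3 (3.94 ± 0.57) and LAMB4 (3.88 ± 0.43) were furthest higher. The cancer-testis gene CT47C1, IGLL3P, TBX5-AS1, KIF25 and CLEC4E were at least 83.5, 51.6, 44.1, 31.9 and 28.7-fold lower. With PF-06821497, HIF1A-AS3 (ratio 16.1, 5.3 to 80.1), GPR15LG (3.68 ± 0.54), PLA2G3 (3.33 ± 0.58), SLURP1 (3.25 ± 0.56) and FAM181A-AS1 (3.18 ± 0.42) were furthest higher. CLEC4E was at least 25.7-fold lower, and FOXN4, KIF25, TBX5-AS1 and TCL1A had ratios from 0.01 to 0.0192, their counting intervals running from 0.00025 to 0.072. With CPI-1205, LINC03013 (4.59 ± 0.74), ARG1 (ratio 24.4, 6.51 to 205), LAMB4 (4.20 ± 0.43), VIT (4.02 ± 0.41) and IGHA1 (3.73 ± 0.95, and 1.5, not past the threshold, without CPI-1205 library 1) were furthest higher. TFF1 and OR2I1P had ratios of 0.00167 (0.000202 to 0.00605) and 0.0014 (3.53e-05 to 0.00782), and HLA-DQB2, PPBP and FOXN4 were at least 51.9, 46.9 and 34.9-fold lower.

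Valemetostat and tazemetostat both carry a pyridone amide, on a benzodioxole core in valemetostat and a biphenyl core in tazemetostat, and they differed in 4459 genes at the matched dose and time. With valemetostat 2551 were higher and 1908 lower. MHC class II genes were higher in 13 of 15 (HLA-DPA1 4.06 ± 0.39), cytokine genes in 28 of 37 (CXCL10 4.67 ± 0.41) and developmental transcription factors in 34 of 82 with 6 lower (FOXA2 2.49 ± 0.24), or 14, 30 and 41 adjusted over the list alone. Basal and squamous genes were lower in 20 of 49 with 1 higher (CALML5 -2.31 ± 0.26) and cholesterol synthesis genes in 13 of 28 (SCD -1.28 ± 0.18), or 22 and 21 adjusted over the list alone. These 5 lists had camera adjusted p 2.07e-16, 2.07e-16, 1.18e-07, 7.19e-10 and 7.74e-09, or adjusted p = 0.0898, 0.0898, 0.11, 0.185 and 0.138 with an estimated correlation. The mouse-tissue measure was 0.65 with valemetostat and -0.07 with tazemetostat, and with it as a covariate 27 transcription factors were higher, their median going from 1.02 to 0.70. Transcription factors numbered 20 higher without valemetostat library 3 and 22 without tazemetostat library 3, and 3, 2 and 3 lower without valemetostat libraries 1 and 3 and tazemetostat library 1. Without valemetostat library 3, 12 basal and squamous and 7 cholesterol genes were lower, and without tazemetostat library 1 or 3, 13 basal and squamous genes. CT47C1 was at least 37.9-fold higher, CXCL9 had a ratio of 178 (counting interval 31.5 to 7090), HLA-DQA2 of 86.7 (15.1 to 3470) and SP8 of 69.0 (18.7 to 577), and ST6GAL1 was higher by 6.01 ± 0.49. LINC01181, LINC03013, LAMB4, DSC1 and LINC02518 were lower, from -3.65 ± 0.49 to -2.97 ± 0.30.

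MAK683 and tazemetostat bind different subunits of the complex, and they differed in 2020 genes, 1549 higher and 471 lower with MAK683. MHC class II genes were higher in 12 of 15 (HLA-DPB1 3.55 ± 0.36), cytokine genes in 20 of 37 (CXCL1 2.85 ± 0.32) and cancer-testis genes in 12 of 33 (PRAME 3.07 ± 0.30), or 12, 29 and 12 adjusted over the list alone. Camera adjusted p was 2.07e-19, 9.2e-18 and 9.71e-06, or adjusted p = 0.0666, 0.0666 and 0.00504 with an estimated correlation. F2RL2 (ratio 152, counting interval 26.8 to 6070), HOXD11 (51.5, 13.8 to 433), ST6GAL1 (5.76 ± 0.49), TFF1 (4.94 ± 0.65) and GGT5 (4.78 ± 0.65) were furthest higher. LINC03013, LAMB4, DSC1, PTPRQ and the osteopontin gene SPP1 were lower, from -2.17 ± 0.60 to -1.81 ± 0.28. LINC03013 was not past the threshold without MAK683 library 1 or 3 or any tazemetostat library, at -2.25 to -1.89. The total was 1272 without MAK683 library 1, 1250 without tazemetostat library 2 and 1270 without tazemetostat library 3. In an overall edgeR test among the 6 compounds, 7100 genes differed, 32.3% of those tested, and 4325 with the processed pseudogene covariate.

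The developmental regulator score, the mean log2 CPM of 108 HOX and developmental transcription factor genes minus the vehicle mean, was 1.81 (SD 0.405) with CPI-0209, 0.96 (SD 0.281) with valemetostat and 1.03 (SD 0.323) with MAK683. It was 0.03 (SD 0.176) with tazemetostat, 0.17 (SD 0.315) with PF-06821497 and -0.07 (SD 0.247) with CPI-1205, against an SD of 0.125 in vehicle. The 95% intervals of the differences from vehicle ran from 1.32 to 2.31, 0.46 to 1.45 and 0.53 to 1.52 for CPI-0209, valemetostat and MAK683. Those for tazemetostat (-0.47 to 0.52), PF-06821497 (-0.32 to 0.67) and CPI-1205 (-0.56 to 0.42) included 0. Two-sided exact permutation tests of 3 against 3 gave p 0.1, the smallest they can give, for CPI-0209, valemetostat and MAK683 (0.2 after Benjamini-Hochberg adjustment over 6 comparisons; all 3 libraries of each above all 3 of vehicle), and 1, 0.5 and 0.7 for the others. Between compounds, valemetostat exceeded tazemetostat by 0.93 (0.44 to 1.42) and MAK683 exceeded it by 1.00 (0.51 to 1.49), while valemetostat and MAK683 differed by -0.07 (-0.56 to 0.42). CPI-0209 exceeded valemetostat by 0.86 (0.37 to 1.35) and MAK683 by 0.79 (0.29 to 1.28). The exact permutation p was 0.1 for each of these (0.136 after adjustment over 15 pairs) except valemetostat against MAK683, where it was 0.6.

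The score rose with the processed pseudogene measure of mouse-tissue reads. Within groups, as deviations from each group's mean, Pearson r was 0.928 and Spearman rho 0.925 over the 21 libraries (permutation p 8e-05 and 1e-04; 0.00016 for r after adjustment over 2 relations). Leaving out the 2 libraries with the most extreme measure gave r 0.902. In the 9 libraries of vehicle, tazemetostat and CPI-1205, r was 0.873 (exact permutation p 0.0324, also after adjustment) and rho 0.833 (exact permutation p 0.0509), and r was 0.734 without the 2 most extreme. With the measure as a covariate, the score differences were 0.95 (0.67 to 1.23) for CPI-0209, 0.67 (0.47 to 0.87) for valemetostat and 0.63 (0.42 to 0.84) for MAK683.

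**Figure D4:**
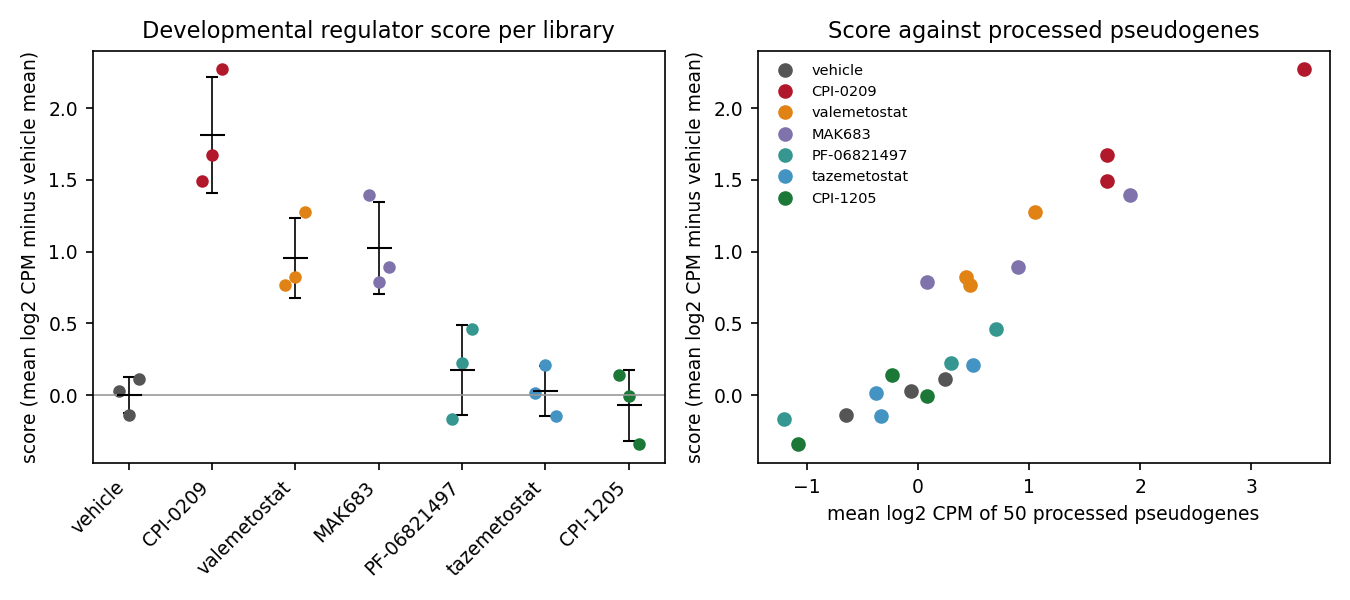
Developmental regulator score per library by group with mean and SD (left, n = 3), and the same score against the mean log2 CPM of 50 processed pseudogenes (right). CPI-0209 library 3 had a score of 2.27, and within groups the measures had a Pearson r of 0.928.

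The 4 compounds with calls changed many of the same genes. Of their calls, 991 genes were higher and 537 lower with CPI-0209, valemetostat, MAK683 and PF-06821497 alike. CPI-0209 shared 3106 higher and 2481 lower genes with valemetostat, where independent calls would share 735.3 and 504.7. It shared 2176 higher and 1073 lower with MAK683 (507.3 and 213.6), and 1162 higher and 733 lower with PF-06821497 (291.4 and 148.4). Across genes, which are not independent replicates, the log2 fold changes of CPI-0209 had a Pearson r of 0.936 with valemetostat, 0.908 with MAK683, 0.766 with PF-06821497, 0.515 with tazemetostat and 0.375 with CPI-1205. All of these comparisons share the vehicle libraries, and 20 simulated sets of unchanged groups with a shared control gave a mean r of 0.488. The covariances, 1.234, 1.006, 0.642, 0.255 and 0.223, compare with a highest simulated value of 0.0507. The simulation drew each gene independently, without variation shared by many genes of a library. Such variation could raise a covariance above the simulated values without a response to the compound.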

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

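The terms and omissions by count column, thinning, both mouse-read covariates, the block from count column numbers and the omission of libraries for lists were chosen only after the data were seen. Of 660 alternative values of 36 counts and scores, 565 stayed within 1.5 times, or for the score within 1 SD. Of 7033 alternative values of 294 named gene changes, 6944 kept their side of the threshold and, where past it, their direction. A further 72 were no longer past it, 16 newly passed it and 1 reversed: TTN with CPI-0209 stood at -0.19 with the processed pseudogene covariate. Changes of direction in genes past the threshold in neither setting were not counted as reversed. Where no reason is given below, the cause was not tested.

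Testing against a 1.5-fold change asks for more and calls fewer genes: 1015 lower with CPI-0209, 1897 higher and 483 lower with valemetostat, 1212 and 108 with MAK683, 412 and 29 with PF-06821497, and 239, 3587, 2001 and 3650 for MAK683, tazemetostat, PF-06821497 and CPI-1205 against CPI-0209, 1527 for valemetostat and 722 for MAK683 against tazemetostat. With no low-count filter, tazemetostat had 43 higher and 3 lower, CPI-1205 124 and 234, and valemetostat and MAK683 differed from CPI-0209 in 1137 and 3241. A fit of only the 2 groups gave 11 higher and 1 lower with tazemetostat, 493 lower with PF-06821497, and 2891 and 5047 for PF-06821497 and CPI-1205 against CPI-0209. DESeq2 called 1 gene higher with tazemetostat, 6 higher and 37 lower with CPI-1205, and 325 between valemetostat and CPI-0209, where limma-voom called 50. Upper-quartile scaling gave 1 higher with tazemetostat. Thinned to the lowest depth, MAK683 had 750 lower and valemetostat differed from CPI-0209 in 5.

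A resubmission term from titles gave 1 higher with tazemetostat and 13 higher and 17 lower with CPI-1205. Without the title-marked libraries these were 3, 57 and 169, and without the column-marked libraries 3, 74 and 185. Each omission leaves 1 library of CPI-1205, which is assumed to vary like the other groups. The term from count columns gave 11 lists for PF-06821497. Library numbers do not pair the samples (deviations of libraries with the same title number had r from -0.313 to 0.326, and 1 of 21 libraries was best correlated with its own number), so the replicate block is only an alternative; with the title term and this block CPI-1205 had 4 higher and 7 lower.

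With the processed pseudogene covariate PF-06821497 and CPI-1205 differed from CPI-0209 in 2292 and 3595 genes, 4325 differed among the compounds, and the score differences were 0.95, 0.67 and 0.63 for CPI-0209, valemetostat and MAK683. With the muscle covariate PF-06821497 had 1215 lower, valemetostat and CPI-0209 differed in 2, and the CPI-0209 score was 1.48. The score was 2.21, 1.26 and 1.32 with a prior count of 0.5 and 2.30, 1.31 and 1.46 as the median over members. An estimated correlation left 1, 1, 1, 0, 1 and 1 lists for CPI-0209, valemetostat, MAK683, tazemetostat, PF-06821497 and CPI-1205, and fry left 0 for tazemetostat and 1 for CPI-1205.

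Leaving out each library in turn, with fewer samples per group, gave from lowest to highest: CPI-0209 4229 to 5088 higher and 3014 to 3747 lower; valemetostat 2641 to 3056 and 1608 to 2397; MAK683 1715 to 2001 and 639 to 813; tazemetostat 0 to 1 and 0 to 0; PF-06821497 750 to 1278 and 291 to 729; CPI-1205 0 to 1 and 0 to 3. Against CPI-0209, valemetostat had 0 to 531, MAK683 685 to 2297, tazemetostat 6652 to 7794, PF-06821497 3412 to 4906 and CPI-1205 6385 to 8015; valemetostat and MAK683 had 2998 to 4069 and 1250 to 1637 against tazemetostat, and 5958 to 8226 differed among the compounds. The score ran from 1.59 to 1.98, 0.80 to 1.05, 0.84 to 1.14, -0.06 to 0.11, 0.03 to 0.34 and -0.17 to 0.07 in the order CPI-0209, valemetostat, MAK683, tazemetostat, PF-06821497 and CPI-1205, and the lists from 18 to 20, 16 to 18, 14 to 20, 2 to 7, 5 to 10 and 7 to 15.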

Other observations

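The tests of the score with the mouse-read covariate, of all tested markers together and of other splits of the samples were chosen only after the results were seen, as were the gene families below; the predictions of the other tests were written before their results were seen.

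The median vehicle level was 0.738 CPM for the 4888 genes higher with CPI-0209 and 39.1 CPM for the 4129 lower, against 7.18 for all tested genes, and 54.9% of the higher genes were under 1 CPM in vehicle. For PF-06821497 the medians were 1.66 and 48.6. A gene near 0 in vehicle passes the low-count filter only with counts in other groups and has little room to fall, which fixes part of this contrast. Protein-coding genes made up 71.4% of the genes higher with CPI-0209, long noncoding genes 13.7% (672) and pseudogenes 13.9% (677, and 276 with the processed pseudogene covariate). Over all tested genes these shares were 70.6%, 18.5% and 9.17%, and among the genes lower with CPI-0209 85.7%, 9.95% and 3.68%. Families in which most tested members were higher with CPI-0209, picked after their values were seen from 438 symbol stems with at least 6 tested coding genes, include HLA genes (19 of 19), CXCL chemokines (13 of 13), APOBEC cytidine deaminases (7 of 8), PSG pregnancy glycoproteins (6 of 7), HTR serotonin receptors (5 of 6), PSMB proteasome subunits (8 of 10) and MMP proteases (12 of 17). Of KDM histone demethylases, 9 of 17 were lower, and of SPRR envelope genes 6 of 11. With the processed pseudogene covariate the numbers were 18, 10, 6, 5, 5, 8 and 9 higher, and 11 and 3 lower. The HOX stems A (6 of 7), B (7 of 7), C (6 of 6) and D (6 of 6) also belong here, and with the covariate 2, 2, 0 and 1 of their genes were higher by edgeR.

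The 991 genes higher with all 4 compounds that had calls had medians of 2.38, 2.15, 1.85 and 1.45 with CPI-0209, valemetostat, MAK683 and PF-06821497. These comparisons share the vehicle libraries. Genes called in opposite directions numbered 3, named here after their values were seen: IQCD (0.47 with CPI-0209 and -0.54 with PF-06821497), ESD (-0.27 and 0.34) and the peptidase gene KLK8 (-0.48 and 0.61).

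The developmental regulator score was higher with CPI-0209, valemetostat and MAK683, and human HOX and developmental genes may be counted from mouse tissue reads. With the processed pseudogene covariate the CPI-0209 difference was 0.95 (0.67 to 1.23), and those of valemetostat and MAK683 also had intervals above 0. The measure may miss part of the mouse tissue reads. It argues against such reads as the whole cause only as far as it follows them. Within vehicle, tazemetostat and CPI-1205, score and measure had a Pearson r of 0.873 (exact permutation p 0.0324, n = 9), so such reads could be part of the cause. The measure is itself higher with CPI-0209, and adjusting for it could remove part of a response of the carcinoma cells. With it as a covariate, the CPI-0209 median of the skeletal muscle markers went from 3.55 to below 0. The adjustment thus took off more than the rise of the markers that the measure was made to follow. With the muscle markers themselves as the covariate, the CPI-0209 score difference was 1.48 (1.06 to 1.9). No biological explanation was tested.

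Tazemetostat and CPI-1205 libraries lay slightly towards CPI-0209. On genes chosen from CPI-0209 against CPI-1205, a contrast without vehicle or tazemetostat, tazemetostat differed from vehicle by 0.282 (-0.097 to 0.661) in the index of higher minus lower genes, with 3 of 3 libraries above all of vehicle, 10.4% of the CPI-0209 difference. On genes chosen from CPI-0209 against tazemetostat, CPI-1205 differed by 0.307 (-0.008 to 0.623), again with 3 of 3 libraries above, 11.2% of it. The choice of genes by the shared vehicle libraries is argued against only as far as vehicle was not in the contrasts that chose them. The fit of all libraries still used vehicle for the filter, scaling and dispersions. Exact permutation p was 0.1 for each, the smallest that 3 against 3 can give, and the intervals include 0. With the processed pseudogene covariate the differences were 0.262 (0.023 to 0.502) and 0.344 (0.081 to 0.607), with intervals above 0. Both differences were taken from the same 3 vehicle libraries. A chance level of these libraries on such genes would shift both compounds alike, so it cannot be told apart from a weak response to both.

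Markers of endothelium, lymphocytes and macrophages were higher with CPI-0209, by 1.46 (1.14 to 1.79) in the mean log2 CPM of all 30 tested members. With the processed pseudogene covariate this difference was 1.06 (0.68 to 1.44), and the median log2 fold change went from 1.80 to 1.07. Over the 21 members called higher, which were picked by their own change, the median went from 2.26 to 1.6 (1.14 to 2.65), with 13 still called, among them PECAM1 (3.63), CLDN5 (3.82) and CD163 (3.76), while KDR (-0.28) and MRC1 (0.29) were not. The difference over all 30 argues against mouse tissue reads, as far as that measure follows them, as the whole cause. Mouse cell types that the measure does not follow and expression by the carcinoma cells may both contribute, and neither was tested.

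Splits of 3 against 3 libraries number 10, too few for a share under 0.05. Against vehicle, the real grouping and the highest other split gave 9017 and 0 genes for CPI-0209, 5987 and 0 for valemetostat, 3415 and 0 for MAK683 and 2098 and 0 for PF-06821497, with 1 split as large in each. For tazemetostat these were 0 and 0 and for CPI-1205 0 and 4, with 10 splits as large. Against CPI-0209 they were 1993 and 0 (MAK683), 8130 and 0 (tazemetostat), 4955 and 0 (PF-06821497), 7736 and 0 (CPI-1205), and 0 and 0 with 10 as large (valemetostat). Against tazemetostat they were 4459 and 0 (valemetostat) and 2020 and 0 (MAK683). Among all 6 compounds, the real grouping gave 7100 genes and the highest of the others 3150. With the real grouping counted, 1 of 100 splits was as large. Chance is thus unlikely there, if the libraries are separate units, which the labels do not state.

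The principal component with the largest variance held 54.4% and the next 8.18%. PF-06821497 library 2, marked as resubmitted in its count column, was most correlated with CPI-1205 libraries 3 and 2 (rho 0.9865 and 0.9858), likewise marked. CPI-1205 library 2 was itself nearest to vehicle library 1 (rho 0.9894). In residuals, PF-06821497 library 2 had correlations of 0.445 and -0.135 with CPI-1205 libraries 3 and 2, which had -0.18 with each other. PF-06821497 library 1, marked in its title, had -0.32 and 0.221 with the same libraries (correlations across genes, which are not independent replicates). MALAT1 and NEAT1 held 0.843% to 1.41% of counts in CPI-1205 libraries and 1.1% in PF-06821497 library 2. Their share was 0.458% to 0.722% in vehicle and 0.633% to 0.859% in CPI-0209 libraries.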
